A study of Mus musculus with 11 samples.

How the data were processed

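RNA was measured by sequencing in mouse embryonic stem cells of the E14 line, grown without feeder cells in medium with serum, LIF and inhibitors of GSK3 and MEK. In the tagged lines SPT16, the large subunit of the histone chaperone FACT, carries a V5 epitope and an auxin-inducible degron, a sequence that lets the plant hormone indole-3-acetic acid (IAA) direct a protein to degradation where the plant receptor TIR1 is present. Cells received 500 nM IAA or the same volume of ethanol (EtOH, the solvent) for 24 hours, per the labels. Libraries were built from total RNA with a NEBNext Directional kit, per the labels' extract protocol.

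The values used are whole-number read counts per gene symbol, which the authors deposited as 1 table without normalization. The submitters' processing notes name STAR, deepTools and the mm10 build. Their versions, the read counter, the gene annotation and the strand setting of the counting are not given in the sources used here. Genes that overlap another gene's exons are therefore uncertain, since reads of the partner could have been counted with them, and members of near-identical families (Usp17l, Zscan4, histone and ribosomal protein genes) share reads in a way that depends on the counter. Beside those marked at their values, the named genes whose exons overlap those of another gene are Aire, Atp5g2, Atp5l, Bax, Ccn2, Ccne2, Cyp51, Dab2, Dnajb9, Grhl2, H3f3a, Hk1, Hmgcs1, Hspa1a, Hspd1, Hspe1, Ifitm2, Itga4, Med31, Mirg, Ncam1, Ndufa4l2, Neurod1, Nnat, Noc2l, Notum, Pcgf5, Pfkp, Phlda1, Pim1, Rian, Rpl13a, Rpl6, Suz12, Tbx3os1, Tigar, Tm7sf2 and Top2a. The authors' deposited comparison table of IAA against EtOH was used only for description. Its base mean, a signal averaged over libraries after division by size factors, its log2 fold change with standard error, its Wald statistic, a score, and its p-value and adjusted p-value are DESeq2 columns, per the file headers. Refitting the deposited counts with DESeq2 and terms for line, replicate number and treatment over all 10 libraries gave log2 fold changes with a median absolute difference of 9.42e-07 from that table, and 7758 calls, the number in that table.

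The count table holds 10 libraries, the labels list 11 samples, and the design text speaks of 12 libraries. Columns carry line codes (10E, 11D and TIR1), while the labels speak of clone numbers and an untagged line, and nothing ties 10E or 11D to a clone number. The tagged lines are therefore called 10E and 11D here. The TIR1 columns were taken as the untagged line because this code alone has an IAA replicate numbered 3 and no EtOH column, as the untagged line has in the labels. Group sizes were 2 for 10E EtOH, 1 for 10E IAA, 2 for 11D EtOH, 2 for 11D IAA and 3 for untagged IAA. The design had assumed 8 tagged libraries, and 7 were analysed. With 1 library for 10E IAA, tests that use it assume that it varies like the other groups. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Replicate pairs differed by more than sampling noise (chi-square per degree of freedom 3.05 to 28.9), so each library counted once.

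Counts were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM factors, filterByExpr on the groups) in R 4.3.3, and a gene was called at a Benjamini-Hochberg false discovery rate (FDR) under 0.05. The comparison of IAA with EtOH used the 7 tagged libraries with line as an additive term. The effect in each line and the line by treatment interaction came from 1 coefficient per group in the same libraries. The comparisons with the untagged line used all 10 libraries, with the tagged lines averaged. Log2 fold changes are given with their standard error (SE), the absolute log2 fold change divided by the square root of F. CPM (counts scaled to library size) are scaled by TMM and given as mean ± SD over libraries. Where a group held 1 to 3 counts in all, the ratio of pooled counts is given with its exact 95% counting interval, and where it held none, a bound against a floor of 3 counts over the group; both cover counting error only, without TMM.

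The design, the processing alternatives, the rule for naming genes and 36 gene lists were set before the data were examined. Named genes were Supt16 and Ssrp1, a panel of 10 pluripotency genes, the 8 highest and 8 lowest called fold changes of IAA against EtOH with a mean of at least 2 CPM and the same sign in both lines, up to 2 called genes per list and direction with the smallest FDR, the 5 highest and 5 lowest called genes of the interaction, and the 6 highest and 6 lowest called genes of each comparison with the untagged line. Predicted genes, Riken clones, pseudogenes and bare identifiers were left out of the ranked sets, some genes that the rule names are not reported here, and other members of a list are named only with values that did not pass. The lists hold markers of cell states and lineages, chromatin and transcription factors, signalling targets, and genes of metabolism, translation, stress and the cell cycle. Some lists share members, so their calls are not independent. Among tested members, 10 of 34 p53 targets, 8 of 19 immediate early genes and 9 of 19 beta-catenin targets are also in another list. Lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 36 lists, with the estimated correlation and the rotation test fry beside it. Called members were also counted with p-values adjusted over the list alone. Genome positions are those of GENCODE vM21 on GRCm38, the assembly also called mm10, which matched 53292 of 55291 symbols.

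The alternatives were RLE size factors, library totals without a composition factor, no filter on low counts, DESeq2 1.42.0, other sets of libraries or covariates, a replicate block and each library left out in turn. Chosen after seeing the data were the design of the deposited comparison fitted in edgeR, all libraries thinned to 3100127 counts, and a fit without the 2 EtOH libraries richest in the transcript CT010467.1, with list counts recomputed in the last and without each library. Relative to TMM, library totals moved the median log2 fold change of IAA against EtOH by 0.33 and RLE by 0.04. Agreement with the untagged comparison was set beside 20 simulated data sets. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

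The fits were tested on counts simulated from the libraries' means and sizes with 100 genes changed 2-fold and 100 changed 4-fold. For IAA against EtOH in both lines, 84% of the former and 95% of the latter were recovered, and 17 of 16594 unchanged genes were called. The shares were 53% and 82% for line 10E, 65% and 90% for line 11D, and 80% and 96% for tagged against untagged cells under IAA. In the comparison of tagged EtOH with untagged IAA, in which no gene was changed, 2 of 16550 unchanged genes were called. Few genes were changed, as many up as down, so these simulations do not cover scaling where most genes change. The changed genes were drawn from those with a mean of at least 2 CPM, so the recovered shares do not cover weaker genes. This self-test was written after a first run of the fits on the real counts. In the real libraries 57.4% of tested genes were called for IAA against EtOH.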

Results

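Gene expression was measured in 10 RNA-seq libraries of mouse embryonic stem cells after 24 hours with IAA or EtOH. FACT, which SPT16 forms with SSRP1, handles nucleosomes during transcription and replication. The series title names the question, whether FACT maintains the expression of pluripotency factors. The SPT16-degron lines 10E and 11D gave 4 EtOH libraries and 3 IAA libraries, and the untagged line gave 3 IAA libraries. Total counts were 7780071 and 11449319 in the 10E EtOH libraries, 3820333 in the 10E IAA library, 3554390 and 11848952 in 11D EtOH, 3100127 and 13510163 in 11D IAA, and 4521137, 6291348 and 11271067 in untagged IAA. On the first principal component, which held 61.2% of the variance, the tagged IAA libraries lay between 94.6 and 97.1 and all other libraries between -44.7 and -34.5. Mitochondrially encoded transcripts took 1.67% to 2.26% of counts in EtOH, 2.45% to 3.16% in tagged IAA and 2.28% to 2.73% in untagged IAA libraries. The transcript CT010467.1 took 2.64% of counts in 10E EtOH replicate 2 and 4.27% in 11D EtOH replicate 1, against 0.129% to 1.58% elsewhere.

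**Figure D1:**
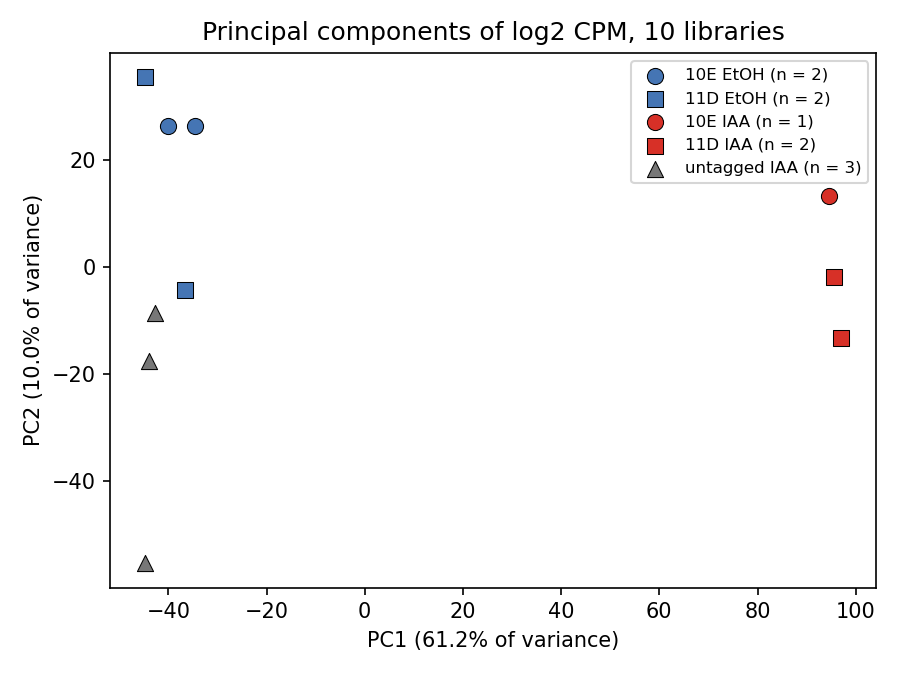
Each point is 1 library placed by its scores on the first and second principal components of log2 CPM, with the share of variance on each axis. The 3 tagged IAA libraries lie at 94.6 to 97.1 on the first axis, and the EtOH and untagged libraries lie at -34.5 or below.

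The transcript of the targeted gene, Supt16 (chromosome 14, positions 52160414 to 52197416, minus strand), stood at 384 and 416 CPM in the 10E EtOH libraries and at 279 in the 10E IAA library. It stood at 364 and 390 CPM in 11D EtOH, at 253 and 286 in 11D IAA, and at 553, 538 and 577 in the untagged libraries. Supt16 was lower in IAA than in EtOH (log2 fold change -0.50 ± 0.09, edgeR FDR 0.000154), and with library totals alone the value was -0.17 with an FDR of 0.0992. Ssrp1 (chromosome 2, positions 85037234 to 85047109), which encodes the partner subunit, fell by more, from 310 ± 22.6 CPM (SD, n = 4) to 146 ± 4.43 (n = 3), a log2 fold change of -1.08 ± 0.09. The degron acts on the protein, which was not measured here, so neither transcript checks the treatment labels. Exons of Supt16 overlap those of Rpgrip1 on the other strand and exons of Ssrp1 those of P2rx3, so both values are uncertain to that extent.

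Core pluripotency transcription factors fell in the tagged lines after IAA. Pou5f1, which encodes OCT4 (chromosome 17, positions 35506018 to 35510772), fell from 802 ± 95.5 CPM (SD, n = 4) to 384 ± 32.7 (n = 3), a log2 fold change of -1.03 ± 0.09. Sox2 (chromosome 3, positions 34650405 to 34652461) fell from 338 ± 114 to 104 ± 21.3 CPM, a change of -1.70 ± 0.22. Nanog (chromosome 6, positions 122707489 to 122714633) fell from 738 ± 70.1 to 193 ± 6.58 CPM, a change of -1.92 ± 0.10. Among factors of the naive state, the log2 fold change was -1.94 ± 0.12 for Esrrb, -1.27 ± 0.17 for Klf4, -1.64 ± 0.12 for Zfp42, -1.52 ± 0.17 for Tbx3, -1.35 ± 0.15 for Prdm14 and -1.38 ± 0.11 for Tfcp2l1. Dppa3, a gene of the early embryo and germ cells, rose from 1.52 ± 0.796 to 7.39 ± 2.12 CPM, a change of 2.10 ± 0.35. The edgeR FDR of these 10 genes was at most 0.000108, the highest being that of Dppa3. Each IAA library lay below all EtOH libraries for the 9 that fell, and the exons of Pou5f1, Tbx3 and Tfcp2l1 overlap those of another gene.

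**Figure D2:**
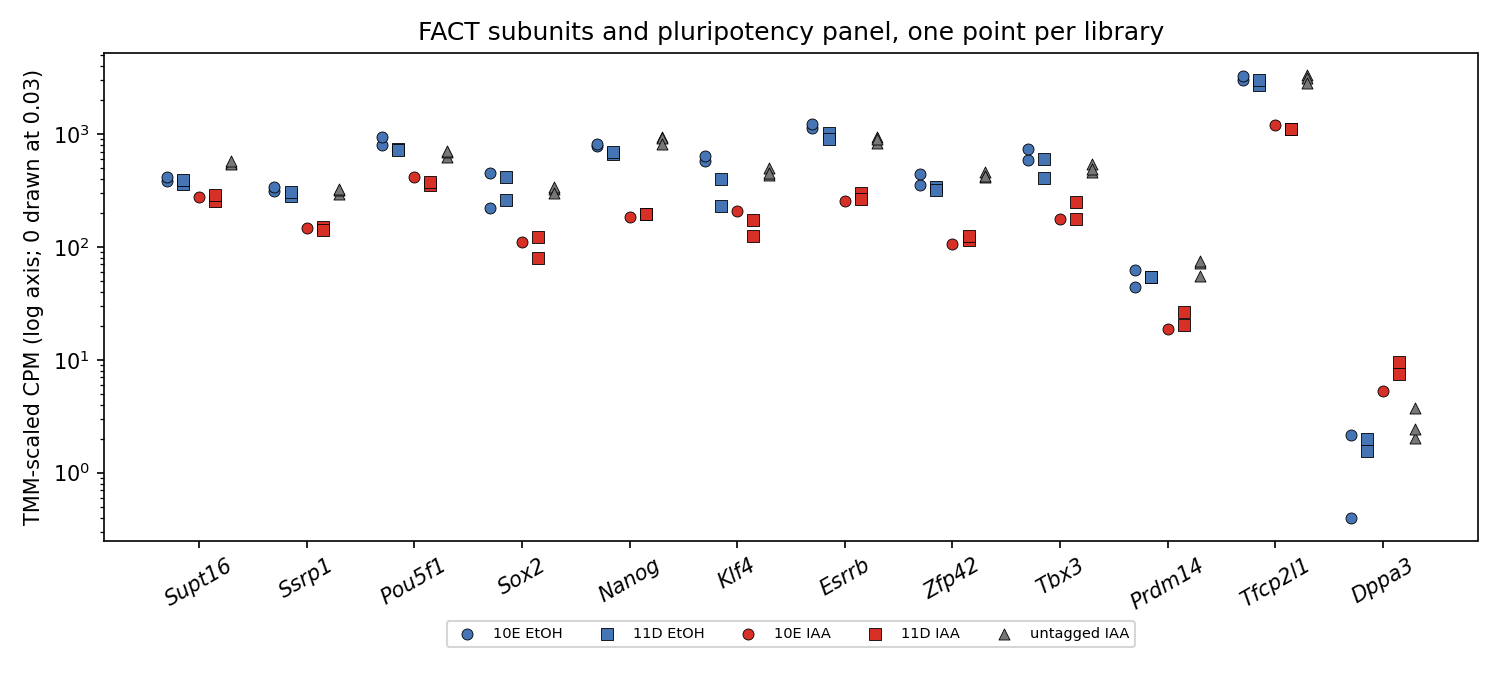
TMM-scaled CPM on a log axis for the FACT subunits and the 10 panel genes, 1 point per library, coloured by treatment and shaped by line. Nanog stands at a mean of 738 CPM in EtOH, 193 in tagged IAA and 897 in untagged IAA libraries, and Dppa3 at 1.52, 7.39 and 2.72.

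Across the transcriptome, 5247 genes were higher and 5034 lower in IAA than in EtOH, out of 17904 tested. A change of at least 2-fold was seen for 3162 of the higher and 1745 of the lower genes. The highest fold changes were in genes at or near 0 in EtOH, among them Cyp1b1, a cytochrome P450 induced through the aryl hydrocarbon receptor (7.38 ± 0.32), and Ptgs2, the inducible prostaglandin synthase (6.53 ± 0.28). Trim67 reached 6.68 ± 0.32 and Rcsd1 5.88 ± 0.33. For Pou4f3, a hair cell transcription factor, 2 counts in all EtOH libraries against 239 in IAA gave a ratio of pooled counts of 203 (exact 95% counting interval 55.5 to 1682). The ratio was 167 (56.7 to 816) for Otog, 95.8 (25.9 to 800.5) for Nlrp10 and 92.1 (31.0 to 451) for Cndp1. The lowest were Mipol1 (-4.96 ± 0.41), Zc3h6 (-3.80 ± 0.55), Chac1, a glutathione-degrading enzyme of the stress response (-3.79 ± 0.29), Tnfaip8l1 (-3.76 ± 0.45) and Gpc6, a heparan sulphate proteoglycan (-3.69 ± 0.55). Il4i1 (-3.49 ± 0.39), the potassium channel gene Kcna2 (-3.42 ± 0.47) and Arhgef38 (-3.34 ± 0.50) followed, and exons of Trim67, Cndp1, Mipol1, Zc3h6, Tnfaip8l1 and Il4i1 overlap those of another gene. Of the genes called higher, 2228 lay under 2 CPM in EtOH, where chemosensory receptor genes, silent in this cell type, also took more counts in tagged IAA libraries (115 ± 4.75 CPM in all, against 61.8 ± 12.8 in EtOH). The split of calls depended on scaling: with library totals alone, which moved the median log2 fold change by 0.33, 7713 genes were higher and 2851 lower, so that 73.0% of calls were higher instead of 51.0%.

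The list of naive pluripotency genes had 31 of 36 members lower and 2 higher, and adjusted over the list alone 32 were lower and 2 higher (camera adjusted p = 9.89e-17; adjusted p = 0.322 with an estimated correlation). Fgf4, a growth factor of the inner cell mass, fell by 2.17 ± 0.10 on the log2 scale, and the higher members were Dppa3 and Fgfbp1 (3.56 ± 0.30). Genes of formative or primed epiblast went both ways, with 8 of 21 higher, 6 lower and 7 not passing, also when adjusted over the list alone (adjusted p = 0.361). Claudin gene Cldn6 (2.52 ± 0.24) and Grhl2 (2.51 ± 0.31) rose, Zic5 (-1.30 ± 0.19) fell, and the mean of this list was 0.49 while its median was -0.00, or 0.33 with library totals. Transcripts of the 2-cell-like state, a rare state of these cultures, had 15 of 23 members higher, also when adjusted over the list alone (adjusted p = 7.79e-05; adjusted p = 0.345 with an estimated correlation). Usp17le (3.53 ± 0.23) and Usp17la (3.00 ± 0.26) rose, members of a family of near-identical copies. By edgeR 0 members of this list were lower, 0 also at an unadjusted p under 0.05, and 0 by DESeq2.

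Germ cell genes, which are methylated in somatic cells, had 16 of 22 members higher and 2 lower, also when adjusted over the list alone (adjusted p = 0.000983; adjusted p = 0.322 with an estimated correlation). Tex101 (4.72 ± 0.52) and Taf7l (4.67 ± 0.49) rose from under 1 CPM in EtOH to 4.60 ± 0.532 and 6.24 ± 1.75 CPM. Genes of the Hox clusters had 9 of 20 members higher and 1 lower, or 8 and 1 adjusted over the list alone (adjusted p = 0.0144; adjusted p = 0.563 with an estimated correlation). Examples were Hoxb9 at 3.18 ± 0.18 and Hoxc4 at -2.35 ± 0.43. That call ended with library totals (adjusted p = 0.0696) and without the 10E IAA library (adjusted p = 0.0531). Without that library, 10 germ cell genes and 5 Hox genes were higher. Of germ cell genes 1 was lower with DESeq2, without 10E EtOH replicate 1 and without each of the 11D libraries, and with library totals both lower calls ended. Lineage markers split. In the trophectoderm list 8 of 18 were higher and 5 lower (adjusted p = 0.695). Members included Krt19 at 2.63 ± 0.39 and Ets2 at -1.77 ± 0.12. Primitive endoderm had 5 of 16 higher and 3 lower (adjusted p = 0.859). Named members were Dab2 at 2.87 ± 0.38 and Lama1 at -1.39 ± 0.10, and both lists gave the same counts adjusted over the list alone.

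Mesendoderm markers were higher for 7 of 14 members and lower for 3, or 9 and 3 adjusted over the list alone (adjusted p = 0.425). Examples were Wnt3 at 4.77 ± 0.50 and Cdx1 at -1.98 ± 0.19. Neural markers were higher for 8 of 16 and lower for 5, also when adjusted over the list alone (adjusted p = 0.783). Members included Neurod1 at 3.51 ± 0.38 and Ncam1 at -1.63 ± 0.11. Fibroblast markers were higher for 4 of 11 members and lower for 0 (0 at an unadjusted p under 0.05 in edgeR and 0 by DESeq2), also when adjusted over the list alone (adjusted p = 0.00766; adjusted p = 0.455 with an estimated correlation). The members that rose included Ccn2 (2.92 ± 0.20), which responds to TGF-beta and YAP signalling in many cell types, while the collagen genes Col1a1 and Col1a2 did not pass (0.12 and 1.05). With library totals 3 neural markers were lower, and 1 fibroblast marker was lower without a filter on low counts or without 11D EtOH replicate 2. Without the 10E IAA library 3 mesendoderm and 5 neural markers were higher and the neural median of 0.42 became -0.34, without 11D EtOH replicate 2 the counts were 4 higher mesendoderm and 3 lower neural markers, and without 11D IAA replicate 2 there were 4 higher and 2 lower neural markers. Mesendoderm markers were higher for 4 members without the line term or in the fit of all 10 libraries. Beside these gains at low levels, chemosensory receptor genes summed to 61.8 ± 12.8 CPM in EtOH, 115 ± 4.75 in tagged IAA and 85.9 ± 23.3 in untagged IAA libraries.

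**Figure D3:**
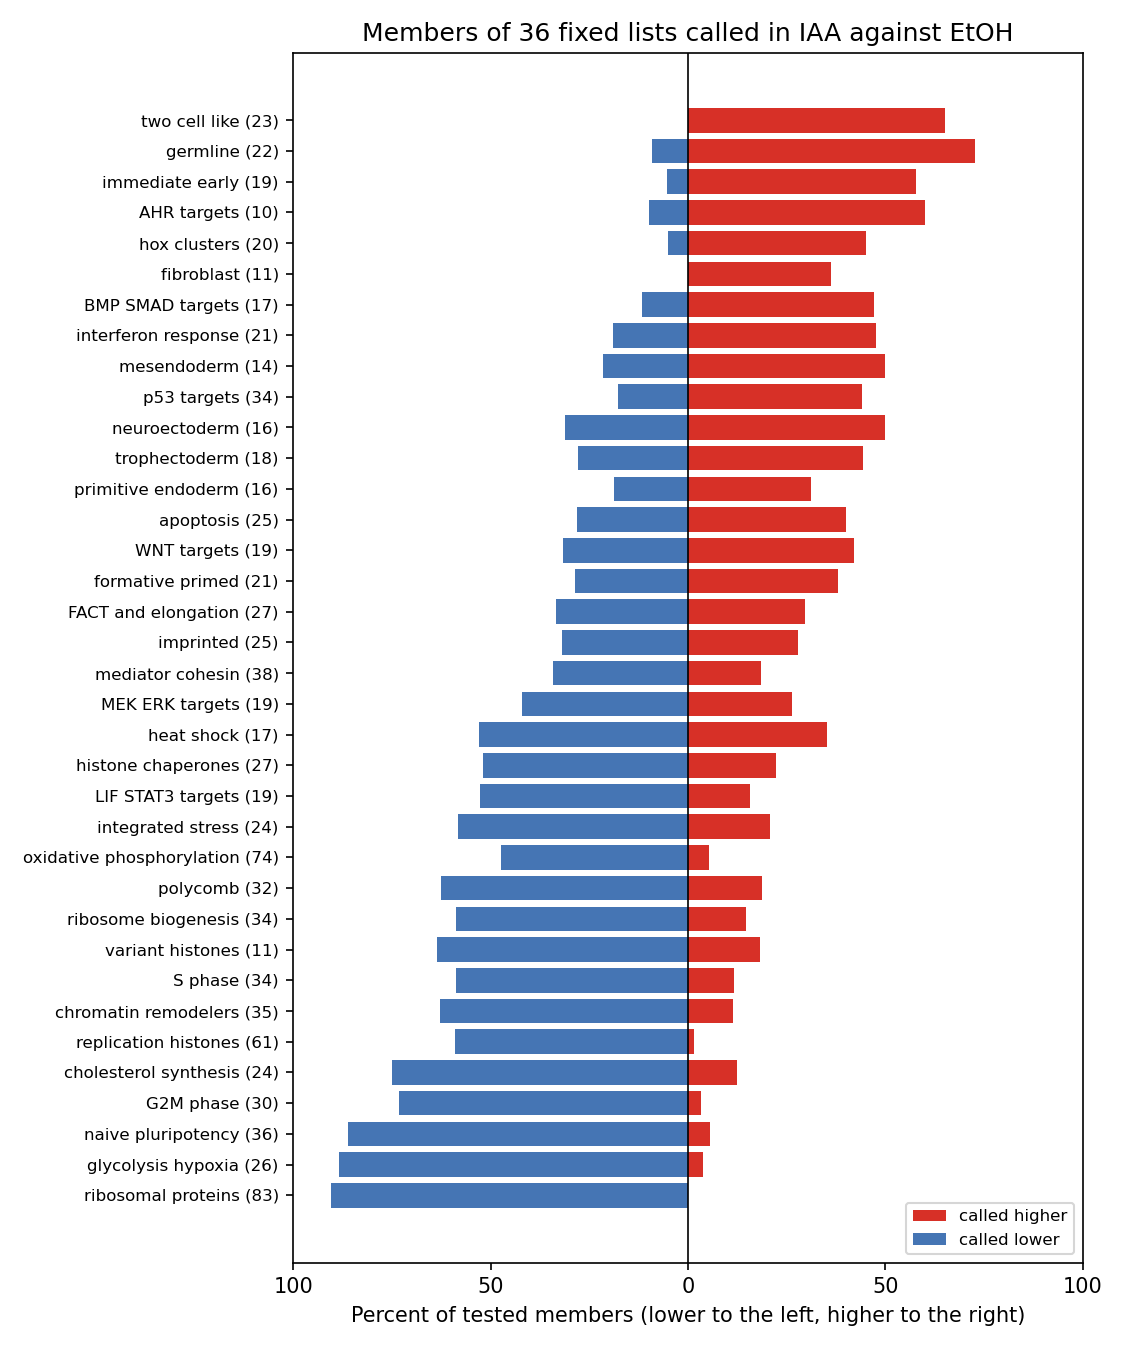
Percent of tested members of each of 36 gene lists called higher (right) or lower (left) in IAA than in EtOH, with the number tested in brackets and TMM scaling. Ribosomal protein genes had 75 of 83 members lower and germ cell genes 16 of 22 higher; with library totals the medians of formative epiblast, histone chaperone, oxidative phosphorylation, ribosome biogenesis, imprinted, and Mediator and cohesin genes are above 0.

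Genes of chromatin and transcription changed in both directions. The list of FACT subunits and elongation factors had 8 of 27 members higher and 9 lower, or 9 and 9 adjusted over the list alone (adjusted p = 0.695). Named members were Hexim1, an inhibitor of the elongation kinase P-TEFb, at 1.78 ± 0.14, Ctr9 of the PAF1 complex at 1.28 ± 0.09 and Aff4 at -0.76 ± 0.09; with library totals 14 were higher and 4 lower. ATP-dependent remodelers were lower for 22 of 35 and higher for 4, also when adjusted over the list alone (adjusted p = 7.79e-05; adjusted p = 0.322 with an estimated correlation). Examples were Arid1a at -1.69 ± 0.13, Atrx at -1.68 ± 0.10 and Chd3 at 0.65 ± 0.15; with library totals 14 were lower and 10 higher. Without the 10E IAA library 1 remodeler was higher, and 2 were without 11D EtOH replicate 1 or 11D IAA replicate 2. Polycomb subunits were lower for 20 of 32 and higher for 6, also when adjusted over the list alone (adjusted p = 0.000711; adjusted p = 0.322 with an estimated correlation). Members included Suz12 at -1.56 ± 0.10, Jarid2 at -1.54 ± 0.09, Pcgf5 at 1.81 ± 0.19 and Bmi1 at 1.31 ± 0.14; 11 were lower with library totals. Histone chaperones other than FACT were lower for 14 of 27 and higher for 6, also when adjusted over the list alone (adjusted p = 0.0804), and their median of -0.25 became 0.08 with library totals (5 lower and 9 higher). The rotation test fry, which asks whether a list moves on balance, passed for the chaperones (adjusted p = 0.00904, lower). Anp32b fell by 1.45 ± 0.11 on the log2 scale and Ubn1, of the HIRA complex, rose by 1.35 ± 0.10, and without the 10E IAA library 9 chaperones were lower.

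Clustered histone genes of the replication-dependent kind were lower for 36 of 61 members and higher for 1, or 36 and 2 adjusted over the list alone (adjusted p = 0.000333; adjusted p = 0.669 with an estimated correlation). The rotation test fry did not pass (adjusted p = 0.200). Against untagged cells under IAA 11 members were lower and 1 higher with a median of -0.18, and the median of tagged EtOH against untagged IAA libraries was 0.86. The linker histone gene H1f5 fell from 355 ± 34.1 to 118 ± 20.9 CPM and H2bc14 from 24.5 ± 3.52 to 7.61 ± 0.866. The number of lower members rested on single libraries, being 23 without 10E IAA replicate 1, 18 without 11D EtOH replicate 1 and 17 without 11D IAA replicate 2. It was 18 with DESeq2 and 16 without the 2 EtOH libraries richest in CT010467.1, where the median of -1.41 became 0.06. With library totals 4 members were higher. The higher call ended with DESeq2, without the 10E IAA library, 10E EtOH replicate 2 or 11D IAA replicate 1, and without those 2 EtOH libraries, while 2 members were higher without 10E EtOH replicate 1. Histone variants outside the clusters were lower for 7 of 11 and higher for 2, also when adjusted over the list alone (adjusted p = 0.361), and 1 was lower with library totals. The centromeric variant gene Cenpa fell (-1.54 ± 0.09), while H3f3b (1.53 ± 0.10) and H3f3a (0.81 ± 0.10), which encode histone H3.3, rose.

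Ribosomal protein genes were lower for 75 of 83 members and higher for 0 (0 at an unadjusted p under 0.05 in edgeR and 0 by DESeq2), or 77 and 0 adjusted over the list alone (adjusted p = 9.89e-17; adjusted p = 0.322 with an estimated correlation). Named members were Rpl13a at -1.32 ± 0.10 and Rpl6 at -1.19 ± 0.09. With library totals 57 were lower and 2 higher, and 1 was higher without 10E EtOH replicate 2. Glycolytic and hypoxia-induced genes were lower for 23 of 26 and higher for 1, also when adjusted over the list alone (adjusted p = 1.14e-09; adjusted p = 0.322 with an estimated correlation). Examples were the phosphofructokinase gene Pfkp at -1.58 ± 0.09 and the hexokinase gene Hk1 at -1.29 ± 0.09, and the higher call ended without the 10E IAA library. Factors of ribosome biogenesis were lower for 20 of 34 and higher for 5, also when adjusted over the list alone (adjusted p = 0.000645; adjusted p = 0.503 with an estimated correlation). Members included Ubtf at -1.35 ± 0.10 and Noc2l at -1.30 ± 0.09; their median of -0.31 became 0.03 with library totals (12 lower, 10 higher). Subunits of oxidative phosphorylation were lower for 35 of 74 and higher for 4, or 34 and 4 adjusted over the list alone (adjusted p = 0.00673; adjusted p = 0.563 with an estimated correlation), and their median of -0.27 became 0.06 with library totals (13 lower, 17 higher, adjusted p = 0.0735). Atp5g2 stood at -1.17 ± 0.12 and Atp5l at 0.98 ± 0.13, and without the 10E IAA library 23 of these genes were lower.

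Of genes highest in S phase, 20 of 34 were lower and 4 higher, also when adjusted over the list alone (adjusted p = 7.79e-05; adjusted p = 0.401 with an estimated correlation). Named members were the polymerase gene Pola1 at -1.67 ± 0.09, Mcm10 at -1.26 ± 0.09 and the cyclin gene Ccne2 at 1.15 ± 0.17; 12 were higher with library totals. The number higher was 2 without 10E EtOH replicate 1, either 11D EtOH library or either 11D IAA library. Of genes highest in G2 and M phase, 22 of 30 were lower and 1 higher, or 25 and 1 adjusted over the list alone (adjusted p = 4.53e-05; adjusted p = 0.345 with an estimated correlation). Examples were Top2a at -1.35 ± 0.10 and Bub1b at -1.19 ± 0.09, and 11 were lower and 4 higher with library totals. The higher call ended without the 10E IAA library, 11D EtOH replicate 1 or 11D IAA replicate 2.

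Immediate early genes were higher for 11 of 19 and lower for 1, also when adjusted over the list alone (adjusted p = 9.05e-05; adjusted p = 0.345 with an estimated correlation). Members included Atf3 at 3.54 ± 0.22, Fos at 2.94 ± 0.23 and Btg2 at 2.26 ± 0.12. The lower call ended with DESeq2 and without the 10E IAA library, 11D EtOH replicate 1 or 11D IAA replicate 2. Targets of p53 were higher for 15 of 34 and lower for 6, or 15 and 7 adjusted over the list alone (adjusted p = 0.00455; adjusted p = 0.322 with an estimated correlation). Pmaip1, which encodes the apoptosis activator NOXA (3.32 ± 0.16), and Perp (3.02 ± 0.15) rose, Bax (-0.79 ± 0.10) and Tigar (-1.11 ± 0.10) fell, and Mdm2 did not pass (-0.10); 23 were higher with library totals. Interferon response genes were higher for 10 of 21 and lower for 4, also when adjusted over the list alone (adjusted p = 0.0252; adjusted p = 0.322 with an estimated correlation). Named members were Zbp1 at 3.42 ± 0.34 and Ifitm2 at -0.69 ± 0.10, and 2 were lower with library totals. The call of this list ended without 11D EtOH replicate 2 (adjusted p = 0.0604). Targets of the BMP and TGF-beta family were higher for 8 of 17 and lower for 2, also when adjusted over the list alone (adjusted p = 0.00756; adjusted p = 0.503 with an estimated correlation). Examples were Id2 at 4.28 ± 0.29 and Smad7 at -1.54 ± 0.16; this call ended without the 10E IAA library (adjusted p = 0.0531). Targets of the aryl hydrocarbon receptor, which binds indoles, were higher for 6 of 10 and lower for 1, also when adjusted over the list alone (adjusted p = 0.000421; adjusted p = 0.322 with an estimated correlation). Members included Cyp1a1 rising from 3.05 ± 3.97 to 144 ± 27.4 CPM and Nfe2l2 at -0.71 ± 0.10.

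Signalling lists of the culture medium had no call. LIF and STAT3 targets were lower for 10 of 19 and higher for 3, or 11 and 3 adjusted over the list alone (adjusted p = 0.0628). Named members were Pim1 at -1.11 ± 0.10 and Osmr at 4.30 ± 0.59. The set test passed without 11D EtOH replicate 2 (adjusted p = 0.00901), without 11D IAA replicate 1 (adjusted p = 0.0339) and without 10E EtOH replicate 1 (adjusted p = 0.0409), and the mean was 0.00 beside a median of -0.39. With library totals 6 were lower and 4 higher, with a median of -0.05. Targets of beta-catenin were higher for 8 of 19 and lower for 6, or 9 and 6 adjusted over the list alone (adjusted p = 0.837). Examples were Dkk1 at 4.67 ± 0.30 and Notum at -1.92 ± 0.19. Targets of MEK and ERK were lower for 8 of 19 and higher for 5, or 10 and 5 adjusted over the list alone (adjusted p = 0.448). Members included Phlda1 at 2.86 ± 0.29 and Spred2 at -1.30 ± 0.11, and a mean of 0.28 beside a median of -0.40. With library totals 5 were lower and 5 higher, with a median of -0.07. Without the 10E IAA library 5 beta-catenin targets were higher, and 4 targets of MEK and ERK were lower and 3 higher.

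Most genes called in either tagged line had the same sign of change in both. Nanog changed by -2.12 in line 10E and -1.79 in line 11D, Cyp1b1 by 8.06 and 6.83, and Ssrp1 by -1.17 and -1.02. Line 10E had 3064 genes higher and 3269 lower, and line 11D had 4143 higher and 4131 lower. Of 9234 genes called in either line, 8964 (97.1%) had the same sign in both, and all 5373 called in both did; 2552 were higher and 2821 lower in both, where independent lists would share 709 and 754. Across 17904 genes, which are not independent replicates, the fold changes of the lines, which share no library, had a Pearson r of 0.790 and a Spearman rho of 0.831. The test of the difference between the lines called 0 genes in edgeR, with 872 at an unadjusted p under 0.05, while DESeq2 called 1. Without a filter on low counts edgeR called 15 higher and 12 lower. Line 10E had 1 IAA library, and the imprinted transcripts Rian and Mirg were far apart between the lines before IAA, Rian at 6.94 and 9.78 CPM in 10E EtOH and 740 and 805 in 11D EtOH. Without 11D IAA replicate 2, line 11D had 2302 genes higher and 2468 lower, and without 11D EtOH replicate 2 it had 2687 higher; DESeq2 called 1660 higher in 10E and 2666 in 11D, and library totals gave 5162 higher and 1462 lower in 10E and 2394 lower in 11D.

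**Figure D4:**
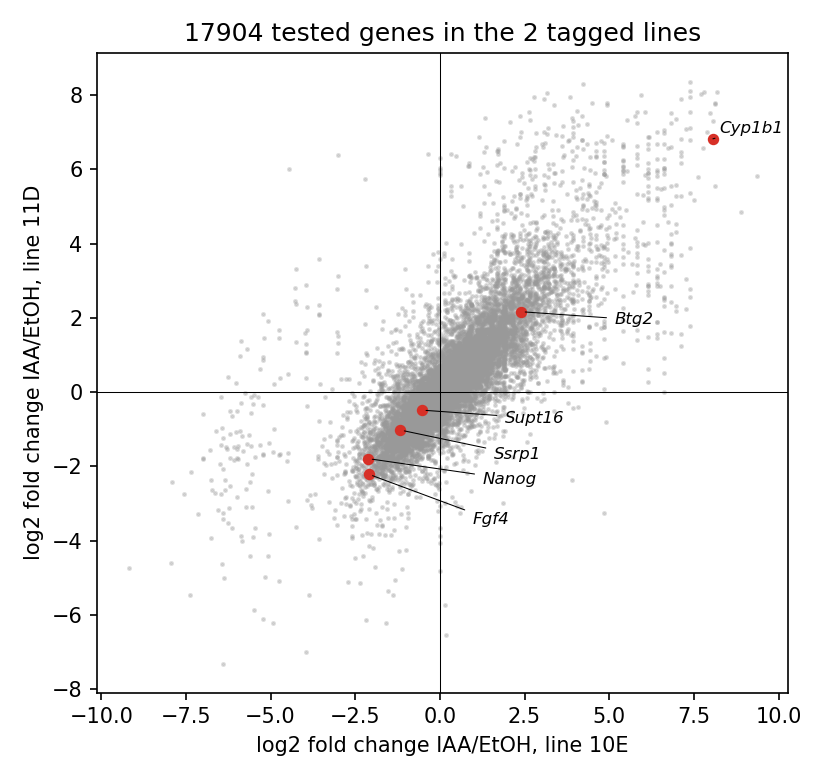
Log2 fold change of IAA against EtOH for 17904 tested genes in line 10E (horizontal axis) and line 11D (vertical axis), with named genes in red. Nanog stands at -2.12 and -1.79 and Cyp1b1 at 8.06 and 6.83.

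The untagged line received IAA without a degron, so it addresses what IAA alone leaves in place, although line and tag cannot be told apart. Under IAA, Nanog stood at 193 ± 6.58 CPM in the tagged lines (n = 3) and 897 ± 68.0 in the untagged line (n = 3), a log2 fold change of -2.23 ± 0.10. Supt16 (-1.02 ± 0.10), Ssrp1 (-1.11 ± 0.09), Pou5f1 (-0.78 ± 0.10), Sox2 (-1.62 ± 0.24) and Esrrb (-1.73 ± 0.11) were lower in the tagged lines, with an edgeR FDR of at most 3.81e-05. Naive pluripotency genes were lower for 28 and higher for 2, ribosomal protein genes lower for 62 and higher for 1, and 2-cell-like transcripts higher for 19. Lists did not all move as far as against EtOH. Subunits of oxidative phosphorylation were lower for 19 and higher for 7, with a median of -0.08 against -0.27. Glycolytic and hypoxia-induced genes were lower for 15 of 25 and higher for 1, with a median of -0.55 against -0.90. Genes of cholesterol synthesis were lower for 11 and higher for 3. The 2-cell-like median was 1.82 against 1.08. The largest gains were in genes absent or nearly absent from the untagged libraries: with 0 counts there and a floor of 3 counts over the group, Pou4f3 was at least 86.1-fold, the integrin gene Itga4 at least 51.5-fold and the prostaglandin receptor gene Ptger3 at least 28.8-fold higher. Ratios of pooled counts were 207 (56.9 to 1715) for Trim67 and 110 (19.4 to 4397) for Dusp15. The lowest were Mipol1 (-7.20 ± 0.59), the Y-linked gene Zfy1 (-6.11 ± 0.54), Arhgef38 (-4.57 ± 0.50), Magea4 (-4.44 ± 0.76), Gpc6 (-4.16 ± 0.48) and Mirg (-4.08 ± 0.24). Zfy1 was also lower in tagged EtOH than in untagged IAA libraries, and Mirg was far apart between the tagged lines before IAA. The values of Zfy1 and Mirg may therefore hold differences that precede IAA. In all, 4865 genes were higher and 4843 lower out of 17439 tested, and 3006 were lower with library totals.

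The comparisons of tagged IAA with EtOH and with untagged cells share the tagged IAA libraries. Of 10112 genes called in the comparison with EtOH, 98.3% had the same sign against the untagged line, where simulated unchanged groups that share those libraries gave 75.7%. With the IAA libraries split by replicate number, so that none was shared, the share was 98.3% of 7957 genes. The correlation across genes was 0.915 (0.537 simulated, 0.892 split), and the covariance 1.60 (0.0535 simulated, 1.33 split), a difference of 1.55 from the simulated value. Higher in both were 4150 genes, and lower in both 4054, of 17283 tested in both, where independent lists would share 1437 and 1386. Parts of the split hold fewer than 2 libraries, so some of the excess over independent lists may come from the shared libraries.

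Tagged cells in EtOH and untagged cells in IAA, of which neither had a degron and IAA together, differed in 622 genes. Nanog (-0.29 ± 0.08, edgeR FDR 0.0696), Pou5f1 (0.25 ± 0.09, FDR 0.123), Sox2 (0.06 ± 0.20, FDR 0.897) and Ssrp1 (-0.02 ± 0.08, FDR 0.891) did not pass, while Supt16 was lower in the tagged lines (-0.52 ± 0.08, FDR 0.00715). Glycolytic and hypoxia-induced genes were higher in the tagged EtOH libraries for 8 of 25 members, and targets of the aryl hydrocarbon receptor were lower for 4 of 10. Cyp1a1 stood at 3.05 ± 3.97 CPM in tagged EtOH (n = 4) and 49.2 ± 37.0 in untagged IAA libraries (n = 3), a log2 fold change of -4.14 ± 0.66, and Cyp1b1 at -3.47 ± 0.88 (FDR 0.0430). The other lowest genes were the X-linked gene Xlr3b (-3.06 ± 0.39), the trophectoderm factor Cdx2 (-3.03 ± 0.41), Nxf3 (-2.73 ± 0.34) and Zfy1 (-2.35 ± 0.25), and the highest Ndufa4l2 (1.89 ± 0.30), Zfp423 (1.78 ± 0.29), Sncg (1.72 ± 0.32), Crmp1 (1.46 ± 0.38), Aire (1.38 ± 0.23) and Tbx3os1 (1.30 ± 0.26). Here 222 genes were higher and 400 lower out of 17439, of which 19 and 73 changed at least 2-fold. With only the libraries compared 78 were higher and 144 lower, without a filter on low counts 643 and 723, with DESeq2 340 were higher and with library totals 715 lower. The counts rested on single libraries: without untagged replicate 1, 17 genes were higher and 66 lower, without untagged replicate 2, 31 and 109, and without 11D EtOH replicate 2, 509 were higher. Without 10E EtOH replicate 1 they were 90 and 126, without 11D EtOH replicate 1, 80 and 157, without 11D IAA replicate 1, 107 and 211, and without 11D IAA replicate 2, 87 and 184; the calls of Cyp1b1, Crmp1 and Tbx3os1 ended in several of these fits, and that of Sncg without untagged replicate 1 (1.64).

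**Figure D5:**
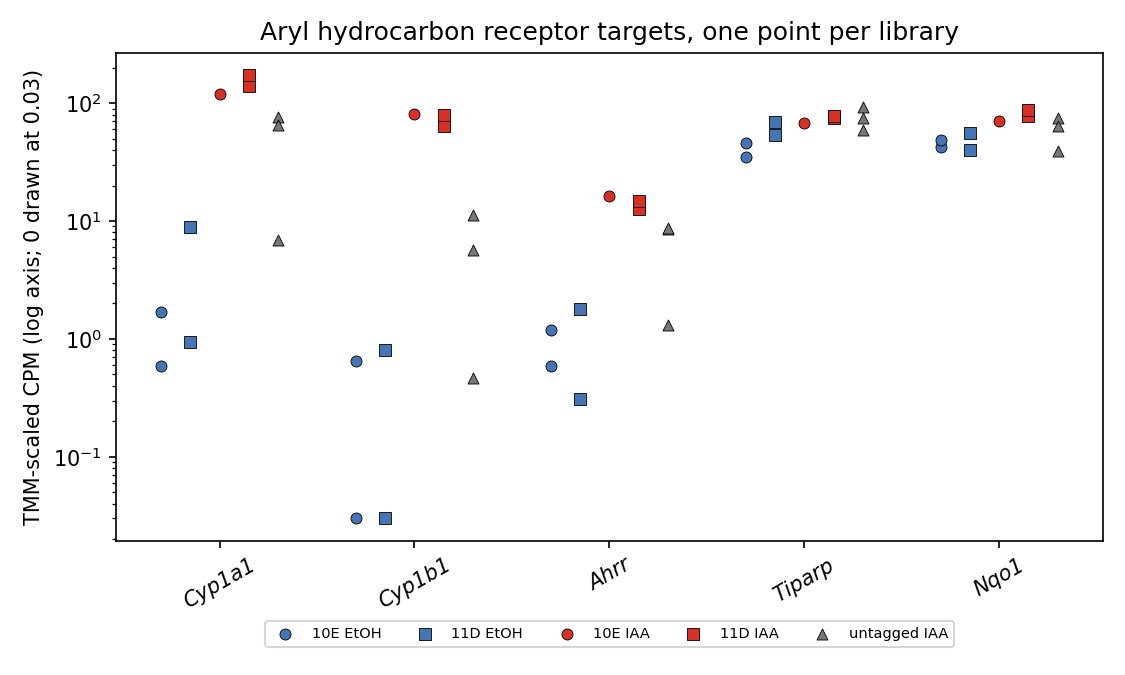
TMM-scaled CPM on a log axis, with 0 drawn at 0.03, of 5 targets of the aryl hydrocarbon receptor, 1 point per library, coloured by treatment and shaped by line. Cyp1a1 stands at a mean of 3.05 CPM in tagged EtOH, 144 in tagged IAA and 49.2 in untagged IAA libraries, with 1 untagged library at 6.89.

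The authors' deposited table of IAA against EtOH holds 3977 genes higher and 3781 lower at an adjusted p-value under 0.05, out of 21210 with an adjusted p-value. For Nanog the authors' deposited table gives a log2 fold change of -1.86, for Ssrp1 -1.01 and for Supt16 -0.43. Over 17904 genes tested here, 96.7% had the same sign as in the authors' deposited table, with an r of 0.993 across genes, which are not independent replicates. The authors' deposited table and the edgeR fit shared 7704 called genes, all with the same sign.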

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

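The tests on sequencing depth, on background reads in genes called in 1 line, on IAA itself and on a partial loss of SPT16 before IAA were chosen only after the result was seen. The other tests were written down before their result, although that on a wrong label of untagged replicate 3 concerns a pattern found in these data. In the 4 tagged EtOH libraries, pooled over both lines, 7 of 157 named genes had 1 library far from the other 3 by Dixon's criterion, and chance flags about 1 in 20. Of these, 3 lay in 10E EtOH replicate 1, 1 in 10E EtOH replicate 2 and 3 in 11D EtOH replicate 2. Groups of 3 or fewer libraries were not tested in this way. In 10E EtOH replicate 1, Atf3 stood at 5.89 CPM against 2.49 to 2.78 in the others, Rad21 at 301.2 against 381 to 398, and Xiap at 97.4 against 136 to 144. In 10E EtOH replicate 2, Spred2 stood at 130.2 CPM against 106 to 109. In 11D EtOH replicate 2, Cyp1a1 stood at 8.96 CPM against 0.593 to 1.70, Kcna2 at 7.26 against 4.15 to 4.45, and Cndp1 at 0.269 against 0 in the others. No biological explanation was tested for these single libraries.

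Weakly expressed genes were higher in tagged IAA than in EtOH libraries, and 2228 of the 5247 genes called higher lay under 2 CPM in EtOH. Depth was excluded, since at equal totals every tagged IAA library detected at least 2274 more genes than every EtOH library (22198 to 22599 against 19330 to 19924, and 19852 to 19899 in untagged IAA). Background reads from genomic DNA may add to weak signals, since chemosensory receptor genes, of which 12 of 20 that passed the filter under 2 CPM were called higher, took 1.86 times the share of counts in tagged IAA that they took in EtOH (112 to 120 CPM against 47.0 to 73.1); untagged replicate 1, with 113 CPM, detected 19871 genes, and untagged replicates 2 and 3 had 75.5 and 69.7 CPM. Genes called higher from the libraries of 1 line alone and under 2 CPM in its EtOH libraries were measured in the other line. There, 98.6% of 877 genes of 10E and 98.1% of 1330 of 11D rose by more than the receptor genes' 95th percentile. Their medians were 1.33 and 1.19, against percentiles of 0.04996 and 0.04537 CPM per kb of exon. For these genes, background reads spread evenly over exon length were therefore excluded as the whole cause. Most receptor genes did not pass the filter, so their percentile does not measure an uneven background. Among genes that passed it under 2 CPM, 60% of 20 receptor genes and 45.16% of 4743 others were called higher. The exact 95% counting interval of the former is 36.05% to 80.88%. A gene can pass the filter by its IAA counts alone, which can raise both shares. Of all genes under 2 CPM in EtOH with known exon length, 12 of 1734 receptor genes and 2142 of 38812 others were called higher. Neither pair of values measures an uneven background, which stays open. The genes called in 1 line hold 1434 of the 2228 genes. For them a change that follows the loss of SPT16 is a hypothesis beside an uneven background. For the other 794, background reads of either kind stay open beside it.

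Targets of the aryl hydrocarbon receptor were higher in untagged IAA than in tagged EtOH libraries for 4 members (Cyp1a1, Cyp1b1, Ahrr and Tiparp), and untagged replicate 3 stood apart. It held Cyp1a1 at 6.89 CPM against 75.7 and 65.1 in replicates 1 and 2, Cyp1b1 at 0.466 against 11.3 and 5.73, and Ahrr at 1.30 against 8.56 and 8.76. Whether replicate 3 is a tagged EtOH library under a wrong label was weighed over 728 genes outside the list called without replicate 3. It lay at a median position of 0.542 (interquartile range 0.390 to 0.717) between the EtOH libraries (0) and untagged replicates 1 and 2 (1). No EtOH library was placed on this scale apart from those that set it, so a wrong label is not excluded. On the second principal component, 11D EtOH replicate 2 (-4.32) lay nearer to replicate 3 (-8.57) than to the other EtOH libraries (26.2 to 35.3). An effect of IAA itself may account for the 4 members in replicates 1 and 2, and it cannot be told apart from the line, because no untagged EtOH library was analysed here. Replicate 3, of the same line and treatment label, lay within the range of the tagged EtOH libraries for all 4 members. For Cyp1a1, Ahrr and Tiparp the top of that range was 11D EtOH replicate 2 (8.96, 1.79 and 69.5 CPM). The other EtOH libraries lay below replicate 3 for these genes. On the scale above, the 4 members had a median position of 0.260 and a highest of 0.351. Neither the line alone nor IAA as labelled accounts for the difference between replicate 3 and replicates 1 and 2, and its cause was not tested.

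Supt16 was lower in tagged EtOH than in untagged IAA libraries (-0.52 ± 0.08). A partial loss of SPT16 before IAA was weighed by the genes called in 10E or in 11D, in the EtOH libraries of the other line against the untagged libraries. Their median shift in the direction of the call was 0.00305 and 0.0257 (log2), with interquartile ranges of -0.21 to 0.21 and -0.24 to 0.28, where their median size after IAA was 1.10 and 1.04. Members went both ways (51.0% and 53.1% in the direction of the call), so this decides nothing, and a partial loss, a difference between the lines and an effect of the tag on the transcript stay open.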

How the results depend on the processing

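The tests chosen only after the result was seen were the design of the deposited comparison in edgeR, thinning and the fit without the 2 EtOH libraries richest in CT010467.1; for IAA against EtOH they gave 4915, 4199 and 4729 genes higher and 4737, 4028 and 4738 lower. Over named genes and alternatives, 2892 values kept their direction and side of the threshold, 64 lost their call and 4 reversed. The self-test changed few genes, all with a mean of at least 2 CPM, and was written after a first run on the real counts. It recovered 84% of 2-fold changes for IAA against EtOH and 53% in line 10E. Without 10E IAA replicate 1 the effect in 10E, the interaction and the agreement of the lines could not be estimated. With 11 samples planned for, the fits over all libraries used 10.

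Where a value moved, the cause was not tested, except that library totals raise the fold changes of IAA against EtOH and of tagged against untagged cells under IAA, the fit without a filter tests more genes, and a fit of only the libraries compared holds fewer samples. Library totals gave 2851 genes lower for IAA against EtOH, 5162 higher and 1462 lower in 10E, 2394 lower in 11D, 3006 lower for tagged against untagged under IAA and 715 lower for tagged EtOH against untagged IAA. DESeq2 gave 1660 higher in 10E, 2666 higher in 11D, 1 higher in the interaction and 340 higher for tagged EtOH against untagged IAA. Without a filter on low counts the interaction had 15 genes higher and 12 lower, and tagged EtOH against untagged IAA had 643 and 723. That comparison had 78 and 144 with only its own libraries. With an estimated correlation 0 lists were higher and 0 lower by camera, against 9 and 12 with the preset one; fry called 10 and 13. Over genes of at least 2 CPM the fold changes of the lines had an r of 0.890. The authors' deposited table holds 3764 calls of at least 2-fold.

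Leaving out each library in turn gave 2302 to 4171 genes higher and 2468 to 4354 lower in 11D, 0 to 2 higher in the interaction, 17 to 509 higher and 66 to 546 lower for tagged EtOH against untagged IAA, and an r between the lines of 0.756 to 0.805. The lowest counts in 11D came without 11D IAA replicate 2, the 2 interaction genes without 10E EtOH replicate 1, and the lowest counts of tagged EtOH against untagged IAA without untagged replicate 1. Without 11D EtOH replicate 2, 11D had 2687 genes higher and tagged EtOH against untagged IAA had 509. The counts of the latter also moved by over 1.5 times without untagged replicate 2 (31 higher and 109 lower), 10E EtOH replicate 1 (90 and 126), 11D EtOH replicate 1 (80 and 157), 11D IAA replicate 1 (107 and 211) and 11D IAA replicate 2 (87 and 184). For Ssrp1 in that comparison the range was -0.068 to 0.0065, with values of 0.0035, 0.0056 and 0.0065 without 10E EtOH replicate 1, 11D EtOH replicate 1 and untagged replicate 3.

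The replicate numbers were not shown to pair the samples: 2 of 3 pairs, those of 11D, could be checked, with a correlation of deviations of 0.181 over 17439 genes. With the replicate block the interaction had 119 genes higher and 128 lower, tagged EtOH against untagged IAA had 142 higher, and Ssrp1 in it stood at 0.0075 instead of -0.02. IAA against EtOH had 5252 higher and 5205 lower with the block.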

Other observations

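No test reported in this part was chosen only after the result was seen. Genes of sterol synthesis and of the integrated stress response were lower in most members after IAA. In cholesterol synthesis 18 of 24 members were lower and 3 higher, also when adjusted over the list alone (camera adjusted p = 0.00673; adjusted p = 0.563 with an estimated correlation), or 9 and 5 with library totals. The synthase gene Hmgcs1 fell by 0.87 ± 0.11 on the log2 scale and Cyp51 by 0.82 ± 0.10, while Tm7sf2 rose by 0.76 ± 0.13. In the integrated stress response 14 of 24 were lower and 5 higher, also when adjusted over the list alone (adjusted p = 0.00862; adjusted p = 0.401 with an estimated correlation), or 10 and 8 with library totals. Atf4, its central transcription factor, fell by 1.48 ± 0.11 and Asns, an ATF4 target, by 1.45 ± 0.09, while Atf3 (3.54 ± 0.22) and the chaperone gene Dnajb9 (1.43 ± 0.16) rose. Heat shock genes parted, with 6 of 17 higher and 9 lower, also when adjusted over the list alone (adjusted p = 0.839), and a mean of 0.32 beside a median of -0.33, or -0.00 with library totals. The inducible Hspa1a (4.48 ± 0.35) and Hspa1b (3.69 ± 0.25), near-identical copies, rose, and the mitochondrial chaperone genes Hspd1 (-0.85 ± 0.09) and Hspe1 (-0.90 ± 0.09) fell.

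Apoptosis genes were higher for 10 of 25 members and lower for 7, also when adjusted over the list alone (adjusted p = 0.170), or 14 and 3 with library totals. Bcl2l11, which encodes the activator BIM, rose by 2.26 ± 0.13, and Xiap, which encodes a caspase inhibitor, fell by 0.89 ± 0.11. Imprinted genes were higher for 7 of 25 and lower for 8, or 7 and 9 adjusted over the list alone (adjusted p = 0.859), with a mean of 0.14 beside a median of -0.12, or 0.22 with library totals. Nnat (5.02 ± 0.24) and Peg3 (1.16 ± 0.10) rose, and Rian (-2.16 ± 0.14) and Mirg (-3.32 ± 0.21) fell; without the line term, 2 imprinted genes were lower and both these calls ended (-1.81 and -2.83). Mediator and cohesin genes were lower for 13 of 38 and higher for 7, also when adjusted over the list alone (adjusted p = 0.0884), or 7 and 17 with library totals, where their median of -0.09 became 0.24. The cohesin genes Stag1 (-1.58 ± 0.10) and Rad21 (-1.33 ± 0.11) fell, and Med14 (0.53 ± 0.10) and Med31 (0.78 ± 0.20) rose. The rotation test fry, which asks whether a list moves on balance, passed for 3 lists that camera did not call, apoptosis genes (adjusted p = 0.0221, higher), Mediator and cohesin genes (adjusted p = 0.0238, lower) and histone chaperones (adjusted p = 0.00904, lower).

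Bias by GC content or transcript length was excluded as the whole cause of the calls of IAA against EtOH: after a trend on both was removed, 92.0% of 10076 called genes with known GC and length kept their call and sign, among them 10 of 10 panel genes. For IAA against EtOH, the real split called 10281 genes and the highest other split of the 35 called 2. So 1 split reached the real value, a share under 0.05 and the smallest that 35 splits can give. Chance is excluded to that extent only, and only if the libraries are independent. The other splits mix IAA with EtOH libraries, so their low counts do not measure how many calls chance could give. For tagged against untagged cells under IAA, 10 splits are too few for a share under 0.05; the real split called 9489 genes and the highest other 0. For tagged EtOH against untagged IAA, the count of splits decides nothing, since in a fit of these 7 libraries with 2 groups and no line term the real split called 0 genes by edgeR, a value that all 35 splits reach. The highest other called 335, with both 10E EtOH libraries and 11D EtOH replicate 1 against the rest, which points to a structure of the samples. In untagged replicate 1, Rn7sk, the RNA of the 7SK particle, took 0.0725% of counts against 0.435% to 1.02% in the other libraries.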
